A study of Rattus norvegicus with 8 samples.

How the data were processed

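Libraries were made from total RNA with an Illumina TruSeq RNA kit and sequenced as paired 100 bp reads on a HiSeq2000. The material was rat placental junctional zone, the layer between the labyrinth and the decidua that makes placental hormones and gives rise to invasive trophoblast. It was dissected on gestation day 14.5 from crosses of Cited2 heterozygous rats, with 4 wild type and 4 Cited2 null samples. The free-text description of most samples speaks of whole placental discs on day 12.5, whereas the sample characteristics and the series design give the junctional zone on day 14.5. The second reading was used throughout. Groups were taken from the sample titles, and the column headings of the deposited table, which carry the same titles beside a wild type or knockout prefix, gave each library its column. No label says whether the samples are separate fetuses, litters or pools, so that p-values measure the spread between these samples.

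The authors mapped the reads to the Rnor_6.0 rat genome with CLC Genomics Workbench 20.0.4, per the labels' protocols. Per the file headers, the deposited values are RPKM (reads scaled by exon length and by the mapped reads of the library) of single transcripts, and all 8 libraries share 1 lane label. The annotation release, the strand setting and the treatment of reads that fit several copies of a gene are not given in the sources used here. The same table holds the authors' own comparison: group means in RPKM, a signed fold change (negative where the null was lower), and an unadjusted and a false discovery rate corrected p-value from a test that the file headers call EDGE with tagwise dispersions. The labels give 0.05 as the authors' cutoff for the latter. The columns used here hold no read counts and no coordinates.

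The table listed 29107 transcripts under 22243 gene names, of which 18309 matched a current symbol or synonym in the GRCr8 gene list, a later build used here for names and for the order of neighbouring genes alone. RPKM were summed over the transcripts of a gene name. Genes that reached 1 RPKM in at least 4 libraries were kept, which left 10431. Values were tested as log2(RPKM + 0.5) with limma 3.58.1 in R 4.3.3 (linear model with group as the only term, trended empirical Bayes variance), and p was adjusted by the Benjamini-Hochberg method with 0.05 as the threshold. All tests were two-sided unless said otherwise. Fold changes are on that scale and understate the change of low genes. The analysis planned for counts was not used because the unit turned out to be RPKM, and the plan named the limma test for that case. For Cited2 and other single values, an exact two-sided permutation test of 4 against 4 libraries was run, whose smallest possible p is 0.0286.

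Before the data were examined, 24 gene lists were fixed: prolactin family, placental cathepsins and serpins, spongiotrophoblast and glycogen trophoblast, trophoblast giant cell, invasive trophoblast, trophoblast stem and progenitor, steroid hormone synthesis, glycogen metabolism, hypoxia response, partners of TFAP2, HIF and CITED coactivators, interferon response, cell cycle, extracellular matrix and proteases, labyrinth trophoblast, fetal endothelial and mesenchymal, decidual and uterine stromal, natural killer cell, macrophage and monocyte, neutrophil and platelet, erythroid, visceral endoderm and yolk sac, immediate early stress, mitochondrially encoded, and Y-linked genes. The 21 lists with at least 5 tested members were tested with limma's camera at a preset correlation of 0.01 between genes, adjusted over the lists, and again with the correlation estimated, with ranks, and with fry, which asks whether a list's genes moved one way on balance and does not compare them with other genes. A few genes belong to 2 lists.

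The rule for genes named in the text was fixed at the same time. It took Cited2, the 12 largest rises and the 12 largest falls among genes past the threshold with at least 1 RPKM in the higher group, no overlap between groups and a symbol that is not a placeholder, and from each list up to 4 members with the smallest adjusted p, or up to 2 where no member passed. Genes named outside this rule are said to be so.

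Absolute depth is unknown. Low values of single-transcript genes stood in whole-number ratios to each other within a tolerance of 0.001, which gave each library's depth relative to wild type replicate 1: 0.937, 0.700 and 0.880 for wild type replicates 2, 3 and 4, and 1.05, 0.909, 0.842 and 0.571 for null replicates 1, 2, 3 and 4. Null replicate 4 was thus the shallowest library and its low values the least precise. The same steps were run on simulated normal values with the mean and variance of each of the 10431 genes, 200 of them changed. The simulated genes were independent of each other, so it does not probe list tests on correlated genes. The test recovered 52.2%, 98.5% and 100% of changes of 0.5, 1 and 2 on the log2 scale, with 2.91% of calls false, and called 0 genes and 0 lists where nothing had been changed.

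Alternatives planned before the data were examined were other pseudocounts (0.1 and 1), no filter, a filter on the mean over all libraries, the replicate number as a block, a minimum log2 fold change of 1, the removal of lists of other cell types, and each library left out in turn. Median scaling, TPM scaling (each library brought to the same RPKM sum), quantile normalization, library quality weights and the test of transcripts one by one were added after the data were seen.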

Results

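RNA was sequenced from the junctional zone of rat placentas on gestation day 14.5, from 4 wild type and 4 Cited2 null samples. The comparison asks which transcripts of this hormone-producing trophoblast layer differ when Cited2, a transcriptional coregulator that binds CREB-binding protein and related coactivators, is missing. Each library listed between 10222 and 10598 genes at 1 RPKM or more. Depth relative to wild type replicate 1 ranged from 0.571 in null replicate 4 to 1.05 in null replicate 1. The 10 most abundant transcripts held between 12.4% and 20.2% of the summed RPKM in wild type and between 8.27% and 10.9% in null libraries. The first principal component (37.8% of the variance) placed every null library above every wild type library, and wild type replicate 2 lay farthest out on the second (16.5%).

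Cited2 itself fell from 318 ± 53.3 RPKM in wild type to 10.3 ± 2.10 RPKM in null junctional zone (SD, n = 4), with no overlap between the groups. The log2 fold change was -4.89 (SE 0.15, limma adjusted p = 2.17e-07; exact permutation p = 0.0286, the smallest that 4 against 4 allows). The authors' deposited table gives a fold change of -31.6 for the same transcript. The residual signal was present in all 4 null libraries, and which part of the transcript it came from cannot be read from a value per transcript.

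Most of the genes that changed were lower without Cited2. Of 10431 genes tested, 94 passed the threshold, 76 of them lower and 18 higher in the null junctional zone, and 20 changed by at least 1 on the log2 scale (18 lower, 2 higher). All 94 separated the groups without overlap, as did 12.2% of the tested genes, where chance gives 2.86%. At an unadjusted p under 0.05 there were 1942 genes. Among genes past the threshold, placeholder names and Cited2 aside, the 3 lowest log2 changes were those of placental prolactin family genes, and the only named rise above 1 was that of Txlnb. The balance of directions reversed under TPM scaling and under no other setting tried. With each library brought to the same RPKM sum, 793 genes passed, 687 higher and 106 lower (86.6% higher, against 19.1% as deposited). That scaling moved the median log2 change of all genes from 0.06 to 0.19. Median scaling, which brought that median to 0.008, gave 16 genes higher and 84 lower. Quantile normalization gave 18 higher and 64 lower. The count was also lower whichever library was left out, and since each such fit has fewer samples, lost power alone would lower the count. It was 23, 62, 23 and 45 without wild type replicates 1, 2, 3 and 4, and 31, 35, 48 and 36 without null replicates 1, 2, 3 and 4.

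**Figure D1:**
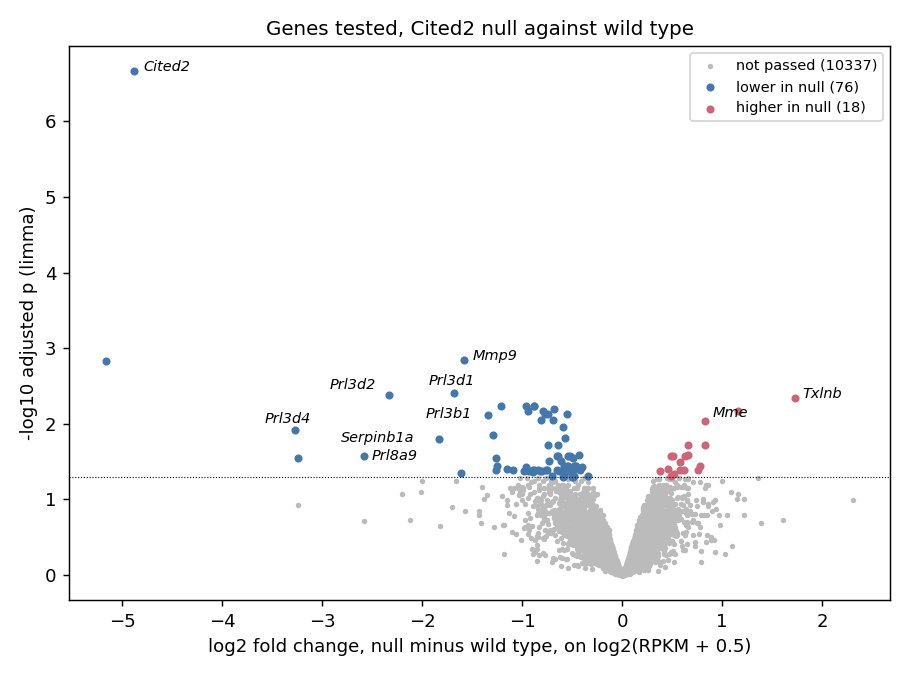
Each point is 1 of 10431 genes, with the log2 fold change of null over wild type on the x axis and the -log10 of the limma adjusted p on the y axis. Blue points are the 76 genes lower and red points the 18 genes higher in null junctional zone, grey points did not pass. The dotted line marks an adjusted p of 0.05. With each library brought to the same RPKM sum, higher genes outnumbered lower ones (687 against 106). They did not under median scaling (16 against 84) or quantile normalization (18 against 64).

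Placental prolactin family hormones were lower, in libraries where decidual (median -0.31) and macrophage (median -0.54) genes were lower too. Prl3b1, a placental lactogen and among the most abundant transcripts of this tissue, fell from 7542 ± 1540 to 2937 ± 353 RPKM (SD, n = 4; log2 fold change -1.35, adjusted p = 0.00772). The other placental lactogen genes fell as well. Prl3d4 fell from 61.3 ± 40.6 to 5.30 ± 2.33 RPKM (log2 fold change -3.27, adjusted p = 0.0122). Prl3d2 (-2.33, adjusted p = 0.00416) and Prl3d1 (-1.69, adjusted p = 0.00391) fell too. Prl8a9 fell from 2278 ± 1279 to 352 ± 131 RPKM (log2 fold change -2.58, adjusted p = 0.0270). Of 18 tested members of the list, 5 fell and 13 did not pass over all genes, and 7 fell when adjusted over the list alone. The median log2 change was -0.84, and it was -0.52 without wild type replicate 3, -0.56 without wild type replicate 4 and -0.27 under quantile normalization. Over all genes 3 members fell without wild type replicate 1, 3 or 4. The list was lower than other genes at the preset correlation (camera adjusted p = 4.01e-08; adjusted p = 0.139 with an estimated correlation). The Prl3d genes are near-identical copies, and the split of reads among them is uncertain. The Prl3b1 call was lost without the filter on low RPKM (adjusted p = 0.128) and under quantile normalization (log2 fold change -0.31, adjusted p = 0.470). That normalization gives each rank the same value in every library, so so abundant a gene can fall there only as far as its rank drops. The Prl8a9 call was lost in 6 of the 8 fits with a library left out.

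Markers of trophoblast giant cells, the polyploid cells at the outer edge of the junctional zone, were lower as a group. Besides Prl3b1, Prl3d1 and Prl3d4, this list holds Mmp9, a gelatinase, which fell from 4.48 ± 0.461 to 1.18 ± 0.244 RPKM (SD, n = 4; log2 fold change -1.58, adjusted p = 0.00145). Of 16 tested members, 4 fell and 12 did not pass over all genes. Adjusted over the list alone, 7 fell and 1 rose, but 4 fell without wild type replicate 2 or 4. Of the 4 called genes, 3 are also prolactin family members, and the other, Mmp9, is also on the matrix and protease list. Over the whole list, 11 members had a negative and 5 a positive log2 change. The median log2 change was -0.32 (camera adjusted p = 8.95e-06; adjusted p = 0.0838 with an estimated correlation), and -0.19 without wild type replicate 4. Decidual and uterine stromal genes moved the same way, with a median log2 change of -0.31. So did macrophage and monocyte genes (median -0.54) and neutrophil and platelet genes (median -0.36).

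The remaining junctional zone lists moved little. Spongiotrophoblast and glycogen trophoblast genes went both ways (17 tested, 0 past the limma threshold, 6 at unadjusted p under 0.05). There were 3 higher and 3 lower when adjusted over the list alone, but 0 without wild type replicate 1 or 3 or null replicate 1 or 2, and 1 higher and 0 lower without wild type replicate 4. Without wild type replicate 2 or null replicate 4 there was 1 lower. Car2, a carbonic anhydrase, stood at 85.0 ± 18.7 and 129 ± 17.6 RPKM in wild type and null (adjusted p = 0.0901). Gjb3, a gap junction protein, stood at 33.2 ± 4.06 and 47.9 ± 10.7 RPKM (SD, n = 4; adjusted p = 0.132). That list was not called (camera adjusted p = 0.444), and its median (-0.02) and mean (0.02) differ in sign, with a downward camera direction. The median ranged from -0.13 to 0.11 with each library left out and was 0.10 under TPM scaling. In the invasive trophoblast list, 1 of 22 tested members fell, the trophoblast keratin Krt7 (397 ± 27.4 to 295 ± 9.15 RPKM, SD, n = 4; log2 fold change -0.42, adjusted p = 0.0412). The Krt7 call was lost without the filter (adjusted p = 0.0919), with the replicate block (0.0705), under quantile normalization (0.0746) and in 7 of the 8 fits with a library left out. When adjusted over the list alone, 2 fell and 1 rose (1 to 3 and 0 to 1 with each library left out). Over all genes Tfpi, a coagulation inhibitor (-0.87, adjusted p = 0.106), Nuak1 (0.42, adjusted p = 0.118) and Plac8 (-0.34, adjusted p = 0.154) did not pass. The invasive list as a whole was called lower (median -0.07, camera adjusted p = 0.0265; adjusted p = 0.241 with an estimated correlation). Its median was 0.07 under TPM scaling and 0.01 without wild type replicate 2 or 4. The call was lost under median scaling (adjusted p = 0.0697), quantile normalization (0.646), with camera on ranks (0.0823), with the replicate number as a block (0.0797) and without wild type replicate 4 (0.0911). Placental cathepsins and serpins (8 tested, 0 passed, 1 at unadjusted p under 0.05, camera adjusted p = 0.205) were not called. Stem and progenitor genes (12 tested, 0 passed, 1 at unadjusted p under 0.05, camera adjusted p = 0.256) were not called either. Neither list had a member that passed when adjusted over the list alone. Their leading members were Ctsj (log2 fold change -0.62, adjusted p = 0.190), Ctsr (0.59, adjusted p = 0.358), Cdx2 (0.50, adjusted p = 0.154) and Ddah1 (-0.55, adjusted p = 0.284).

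Genes of steroid hormone synthesis were lower. Fdxr, which encodes the reductase that passes electrons to mitochondrial steroidogenic enzymes, fell from 9.14 ± 0.875 to 5.82 ± 0.706 RPKM (SD, n = 4; log2 fold change -0.61, adjusted p = 0.0312). Cyp11a1, which makes pregnenolone from cholesterol, stood at 93.6 ± 28.7 and 46.4 ± 13.5 RPKM in wild type and null but did not pass (log2 fold change -1.003, adjusted p = 0.0851). The lipoprotein receptor gene Scarb1 (-0.78, adjusted p = 0.126) and Cyp17a1 (-0.40, adjusted p = 0.154) did not pass either. Of 12 tested members 1 fell over all genes, and 5 fell and 1 rose when adjusted over the list alone. Only 2 fell there without wild type replicate 2, null replicate 1 or null replicate 3, and 3 without wild type replicate 4. The list was called lower (median -0.30, and -0.17 under TPM scaling; camera adjusted p = 0.000136; adjusted p = 0.0838 with an estimated correlation). The Fdxr call was lost without the filter (adjusted p = 0.0615) and in 6 of the 8 fits with a library left out. The decidual and macrophage lists were lower in the same libraries (medians -0.31 and -0.54).

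Matrix and protease genes were called lower as a list, with members that went both ways. Decidual and uterine stromal genes (median -0.31, camera adjusted p = 3.69e-05; adjusted p = 0.147 with an estimated correlation) and fetal endothelial and mesenchymal genes (median -0.14, camera adjusted p = 0.0105; adjusted p = 0.255 with an estimated correlation) were lower in the same libraries. Mmp9 and Mmp2, both gelatinases, fell (Mmp2 from 2.78 ± 0.581 to 0.997 ± 0.366 RPKM, SD, n = 4; log2 fold change -1.16, adjusted p = 0.0394). Lama4, a laminin chain, instead rose from 16.9 ± 1.71 to 25.5 ± 2.75 RPKM (0.58, adjusted p = 0.0324). Plat, tissue plasminogen activator, stood at 18.4 ± 4.34 and 29.9 ± 2.31 RPKM and did not pass (adjusted p = 0.0597). Of 34 tested members 2 fell and 1 rose, and 6 fell and 3 rose when adjusted over the list alone (3 fell without wild type replicate 1). The median was -0.11, but 0.01 under TPM scaling, -0.07 without wild type replicate 1 and -0.19 without null replicate 4 (camera adjusted p = 0.000862; adjusted p = 0.139 with an estimated correlation). The Mmp2 and Lama4 calls were each lost in 7 of the 8 fits with a library left out.

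Interferon response genes were higher as a group although no single member passed over all genes with RPKM as deposited. Of 39 tested members, 36 had a positive log2 change, 0 passed the limma threshold, 27 were at unadjusted p under 0.05, and 24 were higher when adjusted over the list alone. Without null replicate 1 that last count was 11. Under TPM scaling 20 members passed over all genes. Ifi27l2b stood at 39.0 ± 14.2 and 97.5 ± 26.9 RPKM in wild type and null (log2 fold change 1.36, adjusted p = 0.0514). Isg15, a ubiquitin-like modifier induced by interferon, stood at 21.4 ± 5.2 and 43.5 ± 12.4 RPKM (SD, n = 4; 1.002, adjusted p = 0.0570). The authors' deposited table lists both as higher (fold changes 2.43 and 1.97). The median log2 change was 0.60 (camera adjusted p = 3.31e-08; adjusted p = 0.255 with an estimated correlation). The mean log2 level of the list was 2.55 ± 0.252 in wild type and 3.07 ± 0.177 in null libraries, without overlap (exact permutation p = 0.0286). Macrophage and monocyte genes were lower in the same libraries (median -0.54).

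Cell cycle genes all had small positive values. The 38 tested members had a median log2 change of 0.21, 0 passed the limma threshold over all genes or when adjusted over the list alone, and 2 were at unadjusted p under 0.05. These were Ccnb1 (9.98 ± 1.90 and 13.3 ± 2.30 RPKM in wild type and null, adjusted p = 0.198) and Brca1 (3.66 ± 0.576 and 4.61 ± 0.582 RPKM, SD, n = 4; adjusted p = 0.235). The list was called higher at the preset correlation (camera adjusted p = 0.00775; adjusted p = 0.650 with an estimated correlation). The median was 0.10 without either of wild type replicate 3 and null replicate 2. The call was lost under TPM scaling (median 0.32, adjusted p = 0.115), where the median of all genes was 0.19, without wild type replicate 3 (0.177) and without null replicate 2 (0.336).

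Hypoxia response genes were slightly lower as a list (30 tested, median -0.08, camera adjusted p = 0.0265; adjusted p = 0.504 with an estimated correlation). None passed the limma threshold (0 of 30, 7 at unadjusted p under 0.05). Adjusted over the list alone, 1 was lower, the hexokinase Hk1 (14 ± 1.0 and 10 ± 1.16 RPKM in wild type and null, SD, n = 4; adjusted p = 0.0568). Hk2 had a log2 change of -0.27 (adjusted p = 0.144). That count of lower members was 0 without wild type replicate 4 and 2 without null replicate 1. The median was -0.03 without wild type replicate 1, wild type replicate 3 or null replicate 2, and 0.05 under TPM scaling. The call was lost there (adjusted p = 0.0566), under quantile normalization (0.0990) and without wild type replicate 1 (0.256), wild type replicate 3 (0.190) or null replicate 2 (0.171). Partners of TFAP2, HIF and CITED coactivators did not pass (13 tested, 0 past the limma threshold or when adjusted over the list alone, 2 at unadjusted p under 0.05, camera adjusted p = 0.562). Epas1, a hypoxia-inducible factor subunit, stood at -0.34 (adjusted p = 0.162) and the nuclear receptor gene Pparg at 0.26 (adjusted p = 0.233). Under TPM scaling 5 of them were higher when adjusted over the list alone. The glycogen metabolism list was not called (18 tested, camera adjusted p = 0.365). Of its members 0 passed the limma threshold, 3 were at unadjusted p under 0.05, and 15 had a positive log2 change. The list's mean log2 level was 3.38 ± 0.038 in wild type and 3.50 ± 0.093 in null libraries (exact permutation p = 0.0286). Its median log2 change was 0.07, where that of all genes was 0.06. Adjusted over the list alone, 2 were higher, Stbd1, a glycogen-binding protein (18 ± 1.99 and 28.1 ± 4.88 RPKM, adjusted p = 0.0532), and Pygl, a glycogen phosphorylase (18.2 ± 0.933 and 24.1 ± 2.77 RPKM, SD, n = 4; adjusted p = 0.0715). That count was 1 without null replicate 1.

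**Figure D2:**
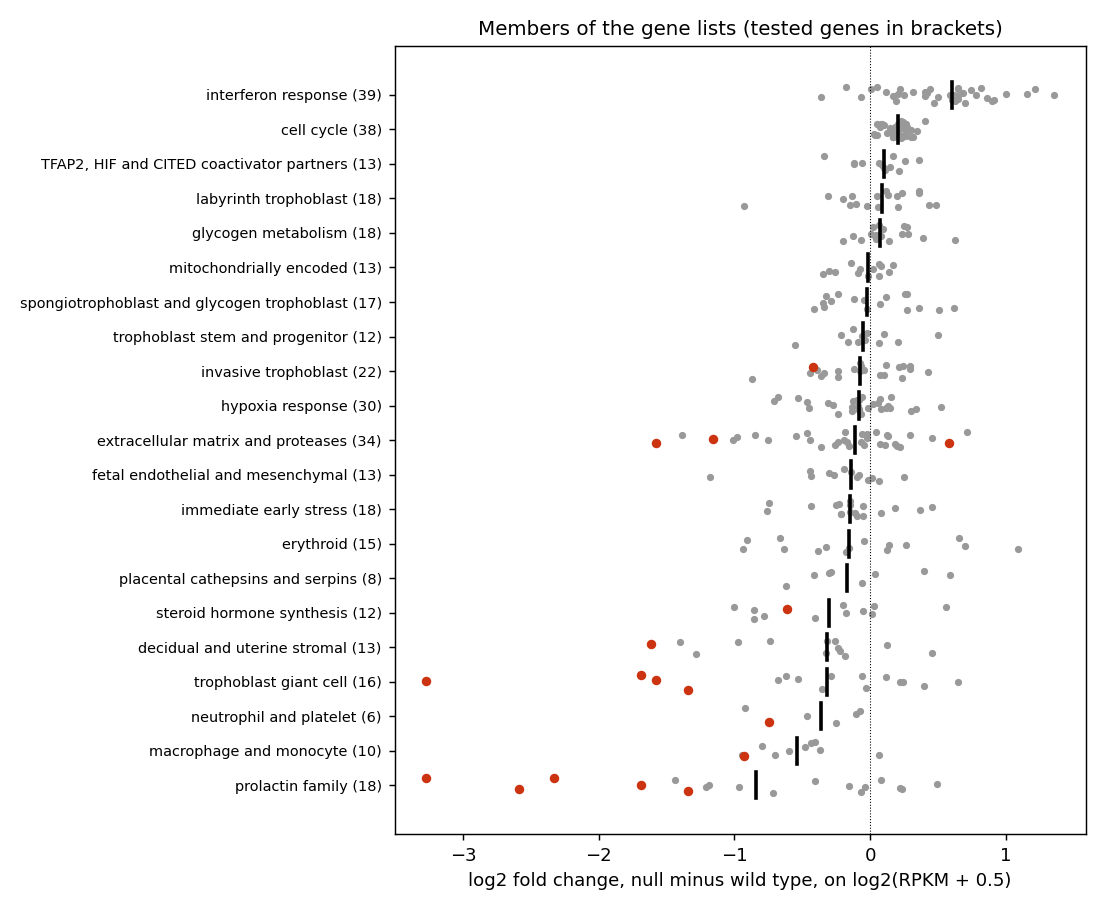
Each point is a tested member of 1 of the 21 gene lists tested, at its log2 fold change of null over wild type. Red points passed the limma threshold over all genes, grey points did not, and black bars are list medians, with vertical scatter added for legibility. Prolactin family members reach from positive values to -3.27, and the interferon list has the highest median, 0.60. TPM scaling turns the small negative medians of the invasive, hypoxia and matrix lists to 0.07, 0.05 and 0.01.

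Markers of other cells in the dissected tissue also differed between the groups. Macrophage and monocyte genes were lower. RT1-Ba, a class II histocompatibility gene, fell from 3.28 ± 0.509 to 1.51 ± 0.419 RPKM (SD, n = 4; log2 fold change -0.93, adjusted p = 0.0418). Cd74, the invariant chain, stood at 10.4 ± 1.31 and 5.63 ± 2.65 RPKM without passing (adjusted p = 0.153). Of 10 tested members 1 fell, and 4 fell when adjusted over the list alone, with Fcer1g (-0.70, adjusted p = 0.107) and RT1-Da (-0.80, adjusted p = 0.136) among them. That count was 1 and 2 without wild type replicates 1 and 4, and 7 without wild type replicate 3 or null replicate 4. The list was called lower (median -0.54, camera adjusted p = 4.70e-07; adjusted p = 0.114 with an estimated correlation). Decidual and uterine stromal genes were lower too. The only member called was Prl8a3, by its symbol itself a prolactin family gene and so a doubtful mark of decidua. It fell from 41.2 ± 15.5 to 13.2 ± 6.0 RPKM (SD, n = 4, log2 fold change -1.61, adjusted p = 0.0453). A2m, a protease inhibitor (-1.40, adjusted p = 0.0694), Mdk (-0.33, adjusted p = 0.0955) and Des, the muscle and stromal filament desmin (-0.97, adjusted p = 0.117), did not pass. Of 13 tested members 1 fell, and 4 fell and 1 rose when adjusted over the list alone. The list was called lower (median -0.31, and -0.19 under TPM scaling; camera adjusted p = 3.69e-05; adjusted p = 0.147 with an estimated correlation). Neutrophil and platelet genes were lower (6 tested, median -0.36, and -0.24 under TPM scaling; camera adjusted p = 0.000745; adjusted p = 0.255 with an estimated correlation). The chemokine receptor gene Cxcr2 fell from 2.13 ± 0.416 to 1.06 ± 0.102 RPKM (adjusted p = 0.0412), and 2 fell when adjusted over the list alone (4 without null replicate 4, and 1 without wild type replicate 1 or 4 or null replicate 1, 2 or 3). Il1b (adjusted p = 0.178), S100a9 (0.213) and Pf4 (0.507) did not pass over all genes. The calls of RT1-Ba, Prl8a3 and Cxcr2 were each lost in 7 of the 8 fits with a library left out.

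Fetal endothelial and mesenchymal genes were called lower (13 tested, median -0.14, camera adjusted p = 0.0105; adjusted p = 0.255 with an estimated correlation) with 0 members past the limma threshold or when adjusted over the list alone. There was 1 at unadjusted p under 0.05, the smooth muscle gene Tagln (log2 fold change -1.18, adjusted p = 0.220). Tie1 stood at -0.43 (adjusted p = 0.328). The list median was -0.25 without null replicate 4 and -0.01 under TPM scaling. Labyrinth trophoblast genes were not called (18 tested, 0 past the limma threshold, 3 at unadjusted p under 0.05, camera adjusted p = 0.444), except without null replicate 4 (0.0458). The list median (0.09) and mean (0.04) were positive and the camera direction downward. The median was -0.06 without null replicate 4, 0.03 without wild type replicate 3 or 4, 0.15 without wild type replicate 1 or 2, and 0.14 without null replicate 1. Under TPM scaling it was 0.20, under median scaling 0.04 and under quantile normalization 0.05. Adjusted over the list alone, 1 was lower, the amino acid transporter gene Slc7a5 (44.3 ± 10.3 and 23.2 ± 6.30 RPKM in wild type and null, adjusted p = 0.0694). Another was higher, the lactate transporter gene Slc16a3 (21.3 ± 1.93 and 27.6 ± 2.65 RPKM, SD, n = 4; adjusted p = 0.0985). Both counts were 0 without wild type replicate 1 or 3 or null replicate 2, and that of higher members also without wild type replicate 4 or null replicate 1 or 4. Erythroid genes were not called either (15 tested, 0 past the limma threshold, 8 at unadjusted p under 0.05, camera adjusted p = 0.102). Adjusted over the list alone, 2 were higher and 2 lower, the latter ranging from 0 to 5 with each library left out. Hbg1 (17.4 ± 4.62 and 39.0 ± 14.7 RPKM, adjusted p = 0.0808) and Hbe1 (224 ± 34.4 and 356 ± 72.1 RPKM, SD, n = 4; adjusted p = 0.0840) had the smallest p. The list was called lower under TPM scaling (adjusted p = 0.0123), with the replicate number as a block (0.0380) and without null replicate 4 (0.0256). Natural killer cell and yolk sac lists had 3 tested members each, too few for a list test. Of the first, 0 passed over all genes (2 at unadjusted p under 0.05, both lower when adjusted over the list alone, Gzmm at -0.44, adjusted p = 0.123, and Il2rb at -0.79, adjusted p = 0.151). Of the second, the lysosomal protease gene Ctsz fell from 102 ± 7.44 to 77.0 ± 1.45 RPKM (adjusted p = 0.0378), also when adjusted over the list alone, while Sox17 (adjusted p = 0.860) and Tf (0.927) did not pass. The Ctsz call was lost in 7 of the 8 fits with a library left out, and under TPM scaling (0.0588).

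Among genes that mark tissue handling, immediate early genes were called lower (18 tested, median -0.14, camera adjusted p = 0.00372; adjusted p = 0.255 with an estimated correlation), a call lost without wild type replicate 4 (adjusted p = 0.0563). Their median was -0.01 under TPM scaling. None of them passed the limma threshold or when adjusted over the list alone (0 of 18, 6 at unadjusted p under 0.05). Adjusted in that way there were 3 lower and 1 higher without null replicate 4, 3 lower under median scaling, 2 lower with the replicate block, 2 lower and 1 higher under quantile normalization, and 1 higher under TPM scaling, where 1 also passed over all genes. Fos stood at 15.0 ± 2.15 and 8.92 ± 2.75 RPKM in wild type and null (SD, n = 4; adjusted p = 0.103) and Junb at -0.25 (adjusted p = 0.145). Mitochondrially encoded genes were not called (13 tested, 0 past the limma threshold, 0 at unadjusted p under 0.05, camera adjusted p = 0.261), except without wild type replicate 2 (0.0359). Mt-nd3 stood at 0.14 (adjusted p = 0.341) and Mt-nd5 at -0.26 (adjusted p = 0.406). Of 3 tested Y-linked genes 0 passed in any of these ways. Eif2s3y was 0.926 RPKM in wild type replicate 2 and between 16.5 and 21.4 RPKM in the other libraries, and Kdm5d (adjusted p = 0.341) was lowest in the same library.

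With the correlation between genes estimated, 0 of the 21 lists passed (6 at unadjusted p under 0.05), and fry called 4: trophoblast giant cell (adjusted p = 0.0122), steroid hormone synthesis, macrophage and monocyte, and prolactin family (adjusted p = 0.0368 each). At the preset correlation 13 passed, 2 higher and 11 lower.

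Among single genes the largest named rise was that of Txlnb, a taxilin known from muscle, from 0.697 ± 0.290 to 3.43 ± 0.691 RPKM (SD, n = 4; log2 fold change 1.73, adjusted p = 0.00457). Rises of 0.83 were found for Mme, which encodes the membrane peptidase neprilysin (6.12 ± 0.875 to 11.2 ± 0.874 RPKM, adjusted p = 0.00909), and for the kinase gene Rps6ka6 (adjusted p = 0.0190). Tp53i3, Ripk3 (a kinase of necroptosis), Rhof, Lgals8 (a galectin), Rbpms, Pdgfd (a growth factor), Lama4, Nqo1 (a quinone reductase) and Fahd1 rose by between 0.77 and 0.52 on the log2 scale. Their limma adjusted p ran from 0.0190 (Lgals8) to 0.0457 (Fahd1). Pdgfd and Fahd1 lost the call whichever library was left out, and also without the filter (limma adjusted p = 0.0870 and 0.0910). Besides the hormone genes and Mmp9, the largest falls were those of Serpinb1a, an inhibitor of neutrophil proteases (14.5 ± 1.88 to 3.99 ± 1.79 RPKM, log2 fold change -1.83, adjusted p = 0.0160) and Fam83f (-1.29, adjusted p = 0.0140). Next came Chrdl2, a chordin-like protein (-1.27, adjusted p = 0.0412), the complement gene C3 (-1.26, adjusted p = 0.0287) and the aspartyl protease gene Bace2 (-1.25, adjusted p = 0.0363). Of the 30 called genes named here besides Cited2, 7 kept their call whichever library was left out (Txlnb, Mme, Mmp9, Prl3b1, Prl3d1, Prl3d2 and Prl3d4), and none reversed direction.

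**Figure D3:**
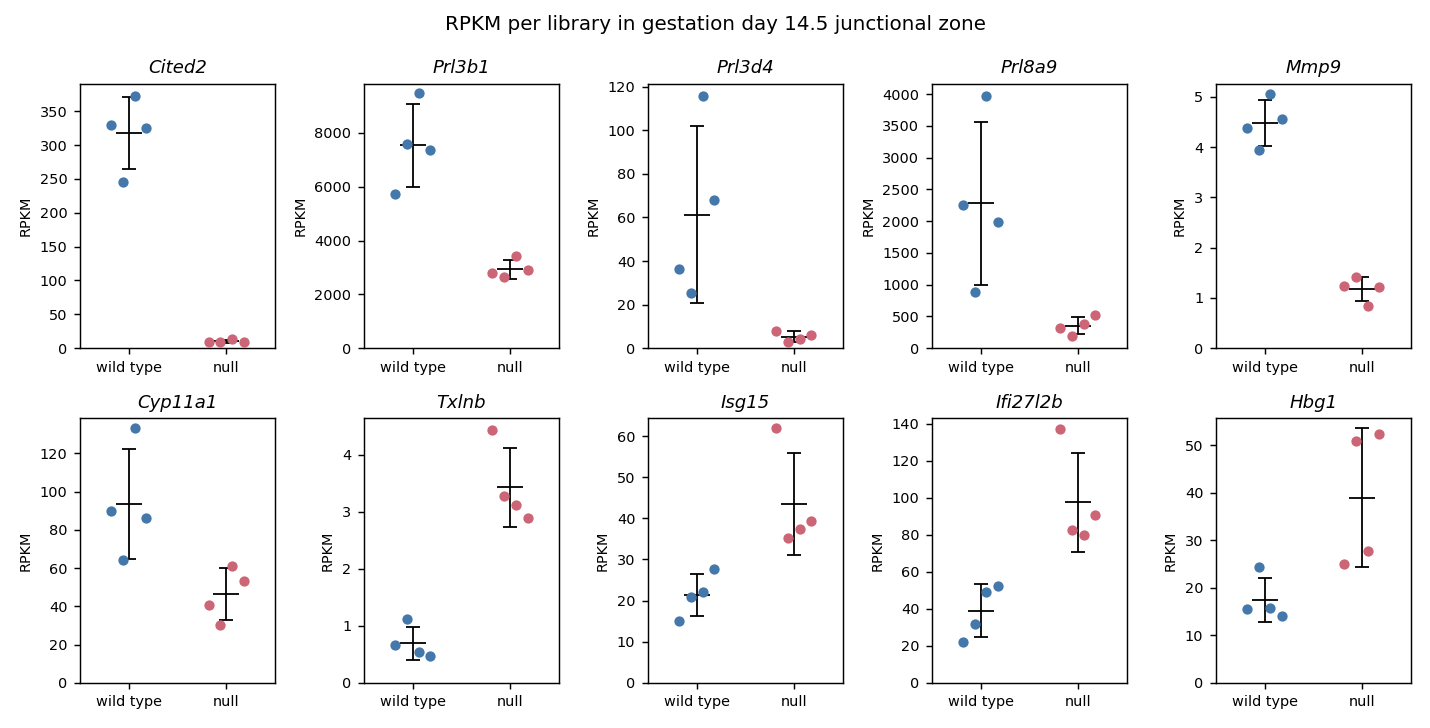
RPKM of 10 genes in each of the 4 wild type (blue) and 4 Cited2 null (red) libraries, with the mean as a bar and the SD as whiskers. Each y axis starts at 0. Cited2, Prl3b1, Prl3d4, Prl8a9, Mmp9 and Txlnb passed the limma test over all genes, while Cyp11a1, Isg15, Ifi27l2b and Hbg1 did not, although none of these 10 genes overlaps between the groups.

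The authors' deposited table lists 43 transcripts of 42 genes past its cutoff, 8 transcripts higher and 35 lower in the null. All 42 genes were tested here and had the same direction, and 17 of them passed here as well, among them Cited2, Prl3b1, Prl3d4, Prl3d2, Prl8a9, Prl8a3, Serpinb1a, Krt7 and Bace2. The other 77 genes called here were not in that table's list. RGD1560112, a gene with a placeholder name chosen after its values were seen, had the lowest log2 change of all (-5.16, adjusted p = 0.00146).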

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

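The tests on dilution by other tissue, on abundant genes, on immune cells, on red cells and on developmental state were chosen after the results they measure were seen. The bounds of the other tests were written before their own values were computed, but after the gene and list results had been seen. Of 206 groups of 4 libraries examined, 12 held a library whose gap to its nearest neighbour exceeded the 5% critical value of Dixon's ratio, where chance gives about 10.3.

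In wild type replicate 2, Eif2s3y (gap 0.947 of the range) and Kdm5d (0.920) stood far below the other wild type libraries, Eif2s3y at 0.926 against 16.5 to 19.0 RPKM. Both are Y-linked, no label gives fetal sex, and without this library 62 genes passed in place of 94. In wild type replicate 3, Fahd1 was low at 2.26 RPKM (0.840), and in wild type replicate 4, Hk1 was high at 15.5 RPKM (0.894) and the immediate early list stood apart (0.870). Among null libraries, Prl8a3 was high in replicate 1 at 22.2 RPKM (0.839). In null replicate 2, Ccnb1 was high at 16.8 RPKM (0.979), A2m was low at 69.3 RPKM (0.852) and the decidual list stood apart (0.890). Chrdl2 was high in null replicate 3 at 0.668 RPKM (0.979) and RT1-Ba low there at 0.889 RPKM (0.841), and Cxcr2 was high in null replicate 4 at 1.21 RPKM (0.891).

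The number of changed genes was larger than in other groupings of the libraries: 1 of the 35 splits into 4 and 4, the real one, gave 94 genes or more, and the highest other split gave 2. For the lists, 5 of the 35 splits gave 13 lists or more, the real one among them, the highest other split giving 14. The others of these 5 mixed 3 libraries of the same genotype with 1 of the other, which keeps part of the genotype contrast. They therefore cannot measure chance alone. Splits with 2 wild type and 2 null libraries on each side, which balance genotype, gave 3 to 7 lists. As lists were called even there, at the preset correlation, chance cannot be excluded for any single list.

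The fall of prolactin family and giant cell genes (30 members, median log2 change -0.38) was weighed first. A dilution of junctional zone by another tissue would lower spongiotrophoblast and glycogen trophoblast genes alike, but their median was -0.0236 and their lower quartile -0.29, which lay above the falling lists' median in each of the 8 leave-outs too. A change in the share of a few abundant transcripts would shift the other genes alike. These transcripts held a smaller share in null libraries, which would raise other genes rather than lower them. Prl3b1, itself a falling member, is among the most abundant, so that share is not independent of the fall. Median scaling brought the median of all genes to 0.008 and left that of the members at -0.44 (-0.53 to -0.39 with each library left out). Under median scaling, this argues against that explanation for the members as a set. Under quantile normalization, which moves abundant genes by construction, the members' median was -0.24 (-0.36 to -0.17), which missed the bound set for both scalings. The test as set, which needed both, therefore did not decide. A smaller share of decidua in the null pieces stays open. With the level of 11 decidual genes as a covariate, prolactin family genes left out of it, the members' median was -0.29. It ranged from -0.53 to -0.20 with libraries left out. Giant cells border the decidua, so that a different dissection edge could remove both. An effect of Cited2 loss on the giant cells or their hormone genes is a hypothesis beside it.

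The rise of interferon response genes was weighed next. More macrophages in the null pieces would raise macrophage genes, whose median was -0.54 with the upper quartile at -0.41. That list rests on 10 tested genes of 23. Adgre1, C1qa and Ptprc lay under the filter, at 0.087, 0.41 and 1.33 RPKM at most. T and B cells had no list, so more of other immune cells cannot be excluded. The rise was not limited to Tap1, Tap2, Psmb8 and Psmb9 of the histocompatibility region, as 36 of the 39 tested members had a positive log2 change. The median without those genes was 0.60, but removing so few could hardly have lowered it, with a lower quartile of 0.24 for the whole list. Nor was the rise limited to a single null library, as the lowest median with 1 of them left out was 0.47. Leaving out wild type replicate 1 lowered the median further, to 0.43, with 17 members higher when adjusted over the list alone. The members varied together (adjusted p = 0.255 with an estimated correlation), so a response that differs between litters could give it too, and the labels name no litters. A response in the trophoblast itself may be the source, as a hypothesis.

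Embryonic globins (Hbe1, Hbz and Hbg1) stood higher and adult globins lower in null libraries, none past the threshold over all genes, and the mean log2 of embryonic minus adult globins was -2.04 ± 0.49 in wild type and -0.53 ± 0.76 in null libraries (SD, n = 4), without overlap (exact permutation p = 0.0286). The difference, 1.51, fell just short of the bound set against a mere difference in red cell share (2 SD of either group). A looser bound of 1 SD, tried for it after its value was seen, was dropped. Yet more or fewer red cells of unchanged makeup would move all globins alike. Here the log2 changes were 0.66 to 1.09 for embryonic and -0.94 to -0.33 for adult globins. For these genes that argues only against a change in the amount of red cells of unchanged makeup. A different mix of red cells in the pieces was not tested and stays open. The log2 ratio of Hbz to summed adult alpha globins, 1.36 higher in the null, fell short of the same bound set against reads shared between copies, which stays open. An earlier developmental state of the null pieces was not decided either: the cell cycle list's mean level gave an exact permutation p of 0.314, and that of stem and progenitor genes, 3.03 ± 0.191 in wild type and 2.995 ± 0.167 in null libraries, leaned the other way (exact permutation p = 0.8286). A slower switch from embryonic to adult red cells may be at work, as a hypothesis.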

How the results depend on the processing

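The scalings, library weights and transcript-wise test were chosen after the data were seen, the other alternatives before. Cited2 kept its call in all 17 alternatives (log2 fold change from -5.01 to -4.75). The count of changed genes, 94, was 36 with no filter (more genes tested), 20 with a minimum log2 change of 1, 47 with transcripts tested one by one, 793 under TPM scaling, and 23 to 62 with 1 library left out (fewer samples). It stayed within 1.5 times at 82 to 101 under the other pseudocounts, filters, scalings and weights and without lists of other cell types (91). The genes were not all the same. Of the 94, 65 were called under quantile normalization, 78 under median scaling and 83 with library quality weights. The 17 of the authors' calls recovered became 10 with no filter, 32 under TPM scaling and 9 to 19 with 1 library left out. The 13 lists became 0 with an estimated correlation and 4 with fry, and were 11 to 15 with 1 library left out. Among uncalled genes, Sox17 turned from -0.10 to 0.134 without null replicate 2 (-0.328 without null replicate 3) and to 0.00128 under TPM scaling. Tf turned from -0.02 to 0.0177 and 0.0499 without wild type replicates 3 and 4 (-0.126 without replicate 1), 0.00927 without null replicate 2 and 0.106 under TPM scaling; the cause was not tested. Of 30 called named genes, 10 kept the call under both pseudocounts, both filters, the block, the scalings and the weights. Whether the replicate numbers of the titles pair the samples was not tested and cannot be told from so few libraries. Same-number correlations ran from -0.11 to 0.29, with 2 of 4 wild type libraries matching their own number best. With the number as a block 67 genes and 13 lists passed, 43 of the genes shared with the 94. Count models, their normalization factors, count filters and voom were planned and not run, since no counts were at hand. Low values of the shallowest library, null replicate 4, are the least precise, and its removal left 36 genes.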

Other observations

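The genes of this part outside the naming rule, and the grouping of histocompatibility genes, were chosen after their values were seen; the test on the neighbours of Cited2 was set before its own value was computed but after the gene results were seen, and the look at the flanking genes came later still.

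Single genes outside the naming rule included the following, and no test of them as groups was run. Inhba, which encodes an activin subunit, fell (log2 fold change -0.82, limma adjusted p = 0.0420), as did Bmp8b (-0.90, adjusted p = 0.0426), Bmp1, a procollagen and chordin protease (-0.52, adjusted p = 0.0270) and Pdgfa (-0.65, adjusted p = 0.0270). The efflux transporter gene Abcg2 rose (0.49, adjusted p = 0.0270) and the protein C receptor gene Procr fell (-0.64, adjusted p = 0.0190). The integrin gene Itgb2 (-0.88, adjusted p = 0.00575), Lsp1 (-0.82, adjusted p = 0.00890) and Nckap1l (-0.70, adjusted p = 0.0496) fell, in libraries where the macrophage list was also lower.

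Of 13 tested class I genes 10 had a positive log2 change and 0 passed in limma (median 0.38), and their summed level was 147 ± 20.8 RPKM in wild type and 205 ± 42.6 RPKM in null libraries (SD, n = 4; exact permutation p = 0.0571). Of 5 tested class II genes 1 was positive and 1 passed, RT1-Ba (median -0.72), the positive one being RT1-DMa (0.64, adjusted p = 0.220), and their sum was 14.5 ± 1.26 and 10.3 ± 2.18 RPKM (exact permutation p = 0.0286). The difference between the classes was not tested, and reads of near-identical class I copies cannot be assigned with certainty.

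Txlnb, the largest named rise, is the tested gene next to Cited2 in the GRCr8 gene order, with 0 tested genes between them, and only 1 of the 10431 genes tested had a larger log2 rise. Among the 40 tested genes nearest to Cited2 it was the 1 called gene, where 0.354 were expected (one-sided Fisher's exact p = 0.302), so a wider effect on the neighbourhood could be neither shown nor excluded. The flanking gene on the other side, Vta1, had a log2 change of 0.20 (adjusted p = 0.234), and the next genes beyond Txlnb, Heca (-0.04, adjusted p = 0.827) and Abracl (0.01, adjusted p = 0.975), did not pass. A local effect of the altered Cited2 allele on Txlnb, rather than a response to the missing protein, may be worth a look as a hypothesis; the call held under every alternative that tested it, with a log2 change of 1.82 under TPM scaling and 1.61 without null replicate 1.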
